A study of Mus musculus with 500 samples.

How the data were processed

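RNA from 500 wells of MIN6 cells in 77 labelled groups was sequenced by the authors after exposure to fatty acids, carriers or drugs. The deposited table held 1 value per gene symbol and well on a log2 scale. Per the submitters' processing notes, reads were handled with STAR, HTSeq and DESeq2 on the build mm10, and no versions or settings are given. The scale was settled from the values themselves, since the name of the file speaks of normalized counts: they ran from 2.09 to 19.1, none was repeated, and the sum of 2 to the power of each value varied between wells by only 2.75% (coefficient of variation; 3075380 to 4026620). Neither the exact transformation nor any batch adjustment by the authors is stated. Read depth is unknown for every well, so no counting interval is given, and the precision is that of the spread between wells. No raw reads were used here.

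The table had 11309 rows, of which 18 whose symbols a spreadsheet had turned into dates were left out because 2 or more genes can give 1 date, leaving 11291 genes. All of them reached the minimum mean of 5 on the linear scale, and 8828 reached 20. Symbols of 10566 genes (93.6%) were found in the mouse annotation of the build GRCm38, which gave the coordinates. Txnip, Cd36, Ins1, Ddit3, Scd1 and the 13 mitochondrial transcripts of a list were not analysed here.

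Each column was joined to its labelled group through the library code in its header. The column headers carry no plate number, so no column was given a plate or a sample by name, no plate term was fitted, and well numbers follow the order of the table. The columns do fall into 6 runs, each opening with a column labelled media, and the labels of each run equal those of exactly 1 plate (6 of 6). The runs therefore stood in for the plates in alternatives chosen after the data were seen, as a block in the fit and left out in turn. No library code occurs more than once within a run, and 2.81% of the variance within groups lay between runs. The deviations of wells from their group means had a median correlation of 0.0158 between wells of 1 run and -0.00201 between wells of different runs.

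Group means were fitted with limma 3.58.1 in R 4.3.3 (empirical Bayes with a trend in the mean, prior degrees of freedom 26.2, residual degrees of freedom 423), and each comparison was a contrast of group means. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the genes of each comparison, and the threshold was an adjusted p of 0.05. Isomer and saturation pairs entered as the mean of the pair differences with equal weights, and chain length and the number of double bonds as slopes over group means. The background for the number of changed genes was the same fit applied to each of 18 BSA plate positions against the other BSA wells. Lists of genes written down beforehand (beta-cell identity, cholesterol synthesis, fatty acid oxidation and synthesis, glycolysis, heat shock, immediate early, ATF4 targets, ER chaperones, lipid droplet, LXR, NRF2, NF-kB and p53 targets, lysosome, mitochondrial transcripts, oxidative phosphorylation, proliferation, ribosomal proteins, other islet cell types and other cell types) were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry. A list needed 3 members in the table. The p-values of lists were adjusted over the lists of a comparison.

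The genes described were named by a rule. It took the 8 largest rises and 8 largest falls among genes past the threshold with a mean of at least 20 on the linear scale and with every well of the group on the same side of the comparison group's mean, up to 4 members of each reported list, and a fixed set (Cmip, Ffar1, Fabp5, Acsl1, Acsl4, Ins2, Hspa5 and Cpt1a in the table). The condition on wells replaced one on plates and was applied to comparisons of single groups only. From the genes so named, those in the text were picked by hand after their values were seen, and 289 gene results were carried through every alternative. Results of some genes that the rule names are not reported here. The media columns, the drug wells at the lowest labelled doses, dodecanoic, 12-methoxydodecanoic and 5(Z)-eicosenoic acid were described because of what their values showed. The summary of the 14 other structural pairs was first the number of pairs above a threshold. After the first run it was changed to the sum over pairs of the numbers of changed genes.

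Alternatives were a stricter minimum mean of 20, quantile normalization, upper-quartile scaling, robust moderation, array weights, a fit of only the groups compared, BSA wells of plate columns 5 and 8 only, and media columns as control. Others were added after the data were seen: 3 components of the residuals as covariates, the runs as a block, each run left out, a fit without 3 BSA wells that stood apart, and leaving out single wells, pairs or acids. For BSA wells left out singly, gene results were kept only where a call changed. Other splits of the wells were counted with a fixed seed. The code was tested on simulated data, in which 50 genes of each size were changed. For palmitic acid against BSA it recovered 11, 39, 50 and 50 of them at 0.25, 0.5, 1 and 2 on the log2 scale and called 8 unchanged genes, and for PAOA_M against PA_M 2, 19, 44 and 50 with 7 unchanged genes called. For E minus Z it recovered 47, 50, 50 and 50, with 8 unchanged genes called. For the slope over chain length it recovered 24, 48, 50 and 50 at 0.025, 0.05, 0.1 and 0.2 per carbon and called 15 unchanged genes. The simulated noise was independent between genes and wells, so these false calls do not cover effects of plate position or run.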

Results

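MIN6 cells, a mouse insulinoma line that secretes insulin and stands in for pancreatic beta cells, were exposed to free fatty acids of many structures, and RNA was sequenced from 500 wells in 77 labelled groups. The library held 62 fatty acids at 0.5 mM for 24 h, with 6 wells for 36 acids, 5 for 24 and 4 for 2. The submitters' series text counts 61 acids and the labels 62; which is extra is unknown. Control wells with bovine serum albumin (BSA), the carrier of the acids, numbered 98 at 18 plate positions, and 6 columns were labelled media alone. Further wells held palmitic acid, oleic acid or both (named PA_M, OA_M and PAOA_M, 4 wells each), and others the endoplasmic reticulum (ER) stressors thapsigargin and tunicamycin at 4 labelled doses each. The deposited values were on a log2 scale for 11291 genes; the read depth of each well is unknown, since the table holds no counts. Each change below is a difference of deposited log2 values with its standard error (±), from limma with p adjusted over all genes of the comparison. That error pools the spread of wells over all groups, so it can be too small for a group whose wells vary more. The wells were the replicates, so p-values measured only the spread between wells of 1 experiment, which may be technical. Runs are 6 stretches of table columns, each with the labels of 1 plate.

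The first question was how far each acid moved the transcriptome. Cpt1a, which encodes the enzyme that admits long-chain acids to mitochondria for oxidation, was higher than in BSA wells in 61 of the 62 acids. Atf3, a stress-induced transcription factor, was higher in 24 acids and lower in 0. Gstp1, a glutathione transferase, was higher in 13 and lower in 1; how reads shared with its near-identical paralog Gstp2 were assigned is not given in the sources used here, so Gstp1 values may include them. Dusp4, a phosphatase induced by growth-factor signalling, was higher in 27 acids and lower in 1. Ins2, an insulin gene, was lower in 7 acids, and Hspa5, the main ER chaperone, was higher in 19 and lower in 10. Cmip, one of the genes fixed for description in advance, was lower in 13. On GRCm38 these genes lie on chromosome 19 from 3322334 to 3385733 (Cpt1a), 1 from 191170296 to 191218039 (Atf3), 19 from 4035407 to 4037985 (Gstp1), 8 from 34807297 to 34819894 (Dusp4) and 8 from 117257064 to 117459430 (Cmip).

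The number of changed genes per acid ran from 3 for 9(Z)-tetradecenoic acid to 5332 for 12-methoxydodecanoic acid, with a median of 353.5 (218 without run 1 and 203.5 without run 6). The same fit, applied to each BSA plate position against the other BSA wells, gave 0 genes at 11 of 18 positions but 291 at position H1 and 194 at H12, so 32 of 62 acids exceeded the highest control position. With array weights 54 did, and all 62 exceeded the median position. By structure, 9 of 12 saturated acids, 6 of 7 Z monoenes with 20 or more carbons, 5 of 12 E monoenes, 8 of 18 acids with 2 or more double bonds, 2 of 3 terminal alkenes, both substituted acids (2 of 2) and 0 of 8 shorter Z monoenes exceeded the highest position. Atf3 was higher in 10 of the 12 saturated acids and in 6 of the 7 long Z monoenes, in 4 of the 12 E monoenes, 2 of the 3 terminal alkenes, 1 of the 18 acids with 2 or more double bonds, 1 of the 2 substituted acids and 0 of the 8 shorter Z monoenes, a contrast that was not tested as a difference between classes. Gstp1 rose in 13 of the 18 acids with 2 or more double bonds.

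**Figure D1:**
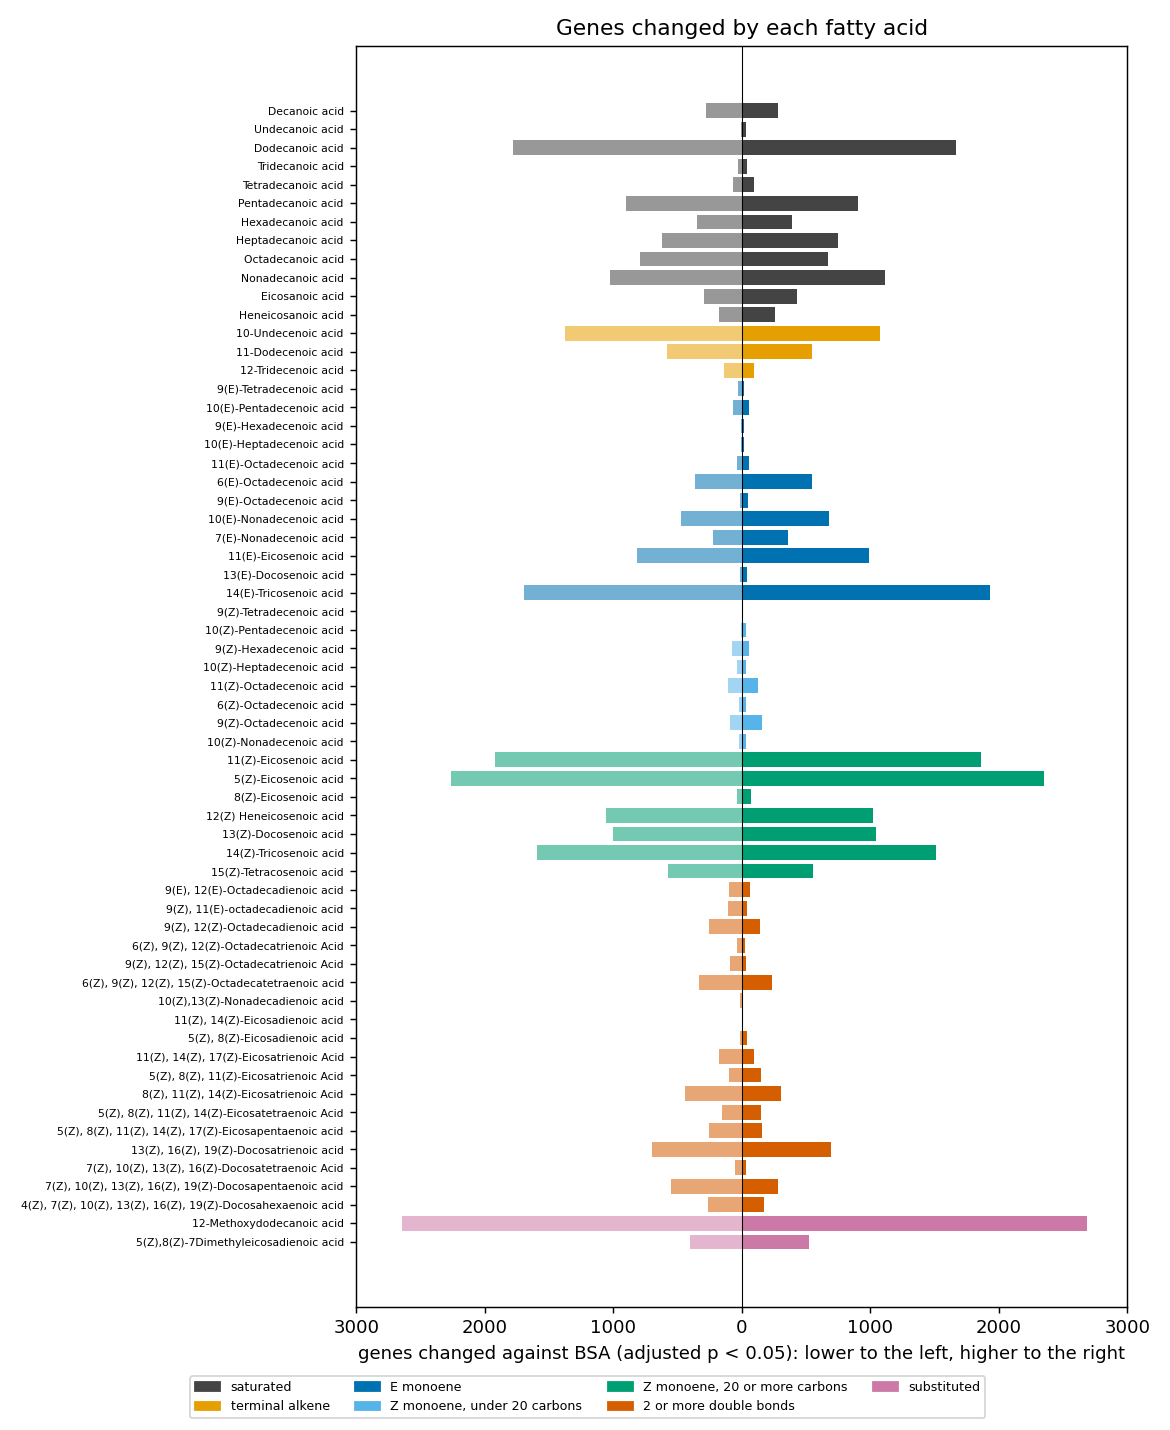
Number of genes changed against BSA (adjusted p under 0.05) for each of 62 fatty acids, lower to the left and higher to the right, coloured by structural class. The longest bars belong to 12-methoxydodecanoic acid (5332 genes) and 5(Z)-eicosenoic acid (4614).

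Gene lists fixed before the data were examined were tested with camera in every acid. Fatty acid oxidation genes were higher in 54 acids and lower in 0, and targets of ATF4, the transcription factor of the integrated stress response, were higher in 32 and lower in 4. Genes of cholesterol synthesis were higher in 20 acids and lower in 23, those of fatty acid synthesis higher in 16 and lower in 22, and targets of the sterol receptor LXR higher in 8 and lower in 26. ER chaperones were higher in 24 acids and lower in 22. NRF2 targets, the antioxidant response, were higher in 14 acids, all of them with 2 or more double bonds. Beta-cell genes were lower in 25 acids and higher in 1, proliferation genes lower in 44 and higher in 1, and immediate early genes higher in 23 and lower in 2. Genes of other islet cell types were higher in 31 and lower in 2, with only 4 of the 10 members of that list tested. The NF-kB list, of which only 3 of 15 members were tested, was higher in 21. Lysosomal genes were higher in 28 and lower in 4, p53 genes higher in 21, heat shock genes higher in 10, lipid droplet genes higher in 6, ribosomal protein genes higher in 10, glycolysis genes higher in 2 and lower in 2, and nuclear oxidative phosphorylation genes lower in 11. Markers of unrelated cell types (6 tested) changed as a list in 0 acids by camera, but single members moved in acids described below, and the 13 mitochondrial transcripts were not analysed here. The members named below had low means over all wells, from 3.76 (Col1a1) to 4.08 (Pecam1) on the log2 scale. With an estimated correlation between genes, fatty acid oxidation was higher in 50 acids, ATF4 targets higher in 29 and lower in 0, NRF2 targets higher in 14, cholesterol synthesis 18 higher and 20 lower, fatty acid synthesis 15 and 19, LXR targets 8 and 23, and ER chaperones 18 and 9. The other lists then had 0 acids higher and 11 lower (beta cell), 0 higher and 8 lower (proliferation), 19 higher and 1 lower (immediate early), 28 and 2 (other islet), 20 and 0 (lysosome), 10 and 0 (NF-kB), 4 and 0 (p53), 3 and 0 (heat shock), 3 and 0 (lipid droplet), 3 and 0 (ribosomal), 1 and 2 (glycolysis) and 0 and 4 (oxidative phosphorylation).

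**Figure D2:**
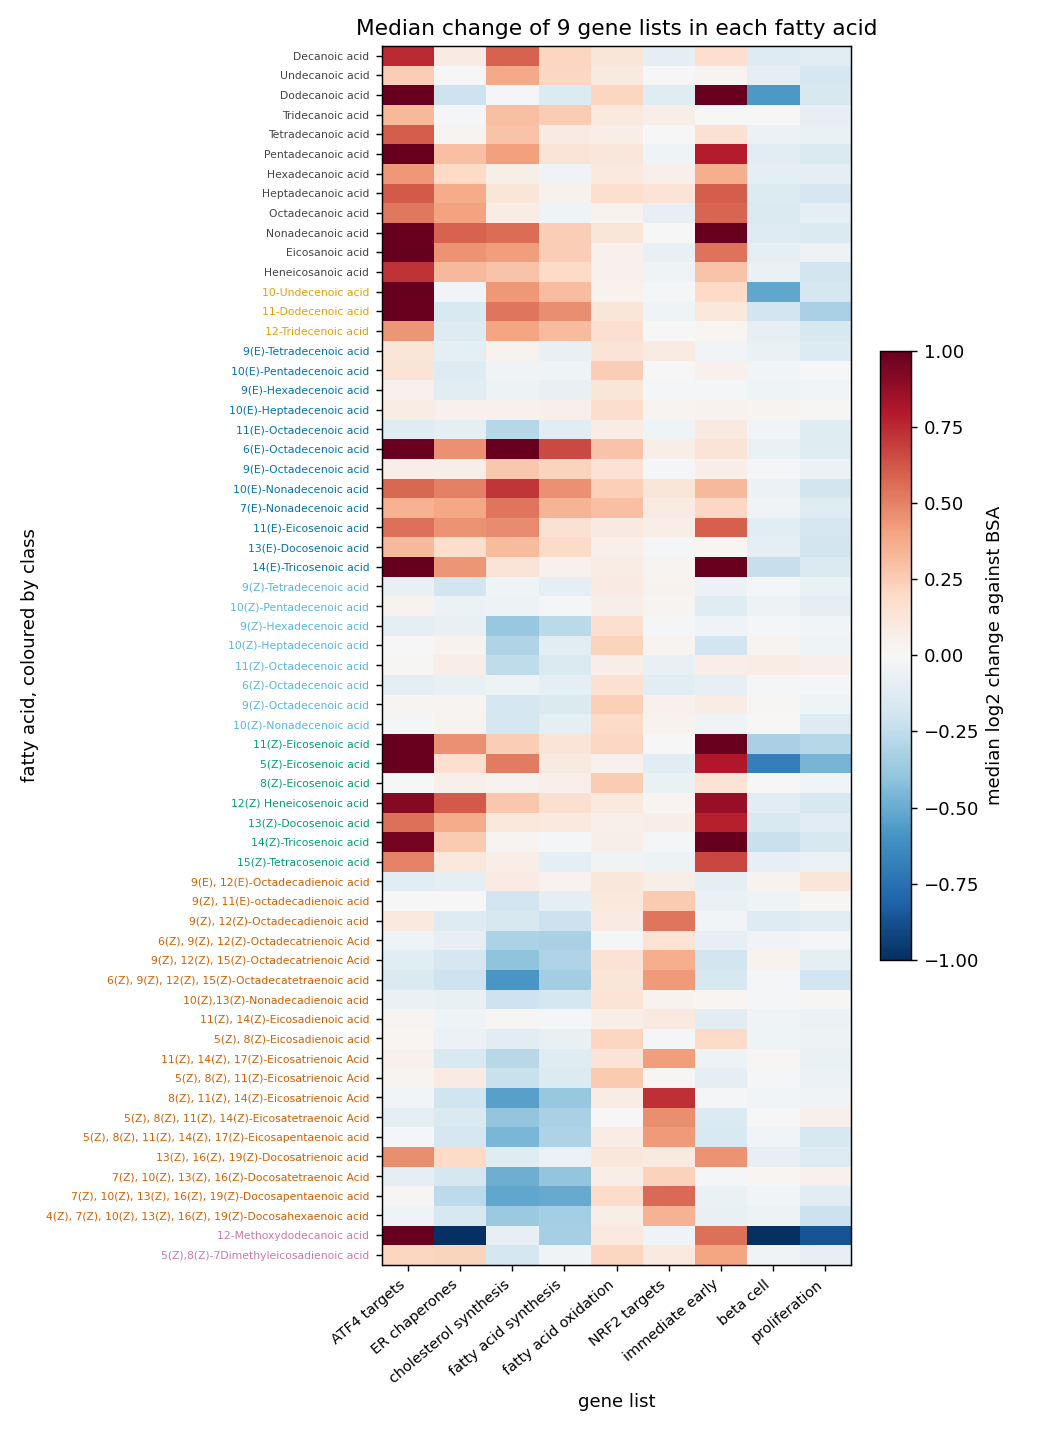
Median log2 change against BSA of 9 gene lists in each of 62 fatty acids, coloured from -1 (blue) to 1 (red), with acid names coloured by structural class. NRF2 targets were higher in 14 acids, all with 2 or more double bonds, and ATF4 targets reached a median of 2.14 in 5(Z)-eicosenoic acid.

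Palmitic acid (16 carbons, saturated, 5 wells) raised Cpt1a by 1.84 ± 0.11 (adjusted p 9.19e-48), with the carnitine carrier Slc25a20 by 0.85 ± 0.10. The stress genes Atf3 (1.01 ± 0.22) and Eif4ebp1 (1.13 ± 0.16), the serine synthesis gene Psat1 (0.78 ± 0.10) and the ER-degradation gene Herpud1 (0.54 ± 0.08) rose as well, and Hspa5 rose by 0.25 ± 0.06. The chemokine Cxcl12 (1.45 ± 0.17), the cholecystokinin receptor Cckbr (1.31 ± 0.18) and Dusp4 (1.27 ± 0.17) were among the largest rises. The ion channel gene Trpm5 changed by -0.68 ± 0.08 and Pdk1, a kinase that restrains pyruvate oxidation, by -0.65 ± 0.10. In all 386 genes were higher and 349 lower. Of the genes fixed in advance, the acyl-CoA ligase gene Acsl4 rose by 0.55 ± 0.13 and the fatty acid binding protein gene Fabp5 fell by 0.45 (adjusted p 0.0252). That call on Fabp5 was lost without well 2 (0.180), 3 (0.193) or 4 (0.154). Further genes of the same rule showed no change that passed: Acsl1 was at -0.01 ± 0.12, the fatty acid receptor Ffar1 at -0.29 ± 0.12 (adjusted p 0.140) and Ins2 at 0.16 ± 0.14. Cmip was at -0.24 ± 0.08 with an adjusted p of 0.0547, which fell to 0.0395 without palmitic well 3, 0.0298 without well 5, and 0.0492 and 0.0411 without single BSA wells at B5 and F8. It was 0.0412 without run 6 and 0.0327 with the runs as a block. ATF4 targets rose (12 of 17 over all genes tested and 15 adjusted over the list alone; median 0.43, camera adjusted p 7.09e-20, 1.42e-04 with an estimated correlation). ER chaperones rose too (7 of 13 over all genes tested and 8 adjusted over the list alone; 2.62e-08 and 0.00141).

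The PA_M wells were a second set with palmitic acid alone. Cpt1a rose by 1.68 ± 0.12, Atf3 by 1.25 ± 0.24, Eif4ebp1 by 1.13 ± 0.18, the cystine transporter Slc7a11 by 1.06 ± 0.21 and Hspa5 by 0.31 ± 0.07, while the synaptic vesicle gene Sv2b changed by -0.94 ± 0.11. Here 425 genes were higher and 360 lower than in BSA wells, and the count fell from 785 to 492 without PA_M well 4, to 500 without well 1 and to 473 without run 1. Without run 1 the Hspa5 call was lost as well (adjusted p 0.0511). Compared directly with the library palmitic acid wells, 2 genes were higher and 6 lower.

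Stearic acid (18 carbons, saturated, 6 wells) raised Cpt1a by 1.87 ± 0.10 and Cckbr by 1.62 ± 0.16. The immediate early gene Egr1 rose by 1.62 ± 0.19, Dusp4 by 1.53 ± 0.15 and Atf3 by 1.27 ± 0.20. The ER co-chaperones Dnajb11 (0.83 ± 0.15) and Sdf2l1 (0.72 ± 0.11) and Hspa5 (0.55 ± 0.06) rose, as did glucagon, Gcg (1.02 ± 0.10), and transthyretin, Ttr (0.96 ± 0.10). The water channel Aqp4 (-1.21 ± 0.18), the iron exporter Slc40a1 (-0.87 ± 0.07) and the activin receptor Acvr1c (-0.79 ± 0.06) fell. In all 673 genes were higher and 792 lower. ER chaperones rose (11 of 13 over all genes tested and 12 adjusted over the list alone; 2.44e-21, 1.09e-07 with an estimated correlation), as did ATF4 targets (13 of 17 over all genes tested and 14 adjusted over the list alone; 1.65e-21 and 3.17e-05). Fatty acid synthesis genes had a median of -0.05, a mean of 0.02 and an upward test that did not pass (0.554).

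Oleic acid (18 carbons, 1 Z double bond, 5 wells) raised Cpt1a by 1.75 ± 0.11, Slc25a20 by 0.80 ± 0.10 and Cox6a2, a respiratory chain subunit gene, by 1.09 ± 0.17. The sterol synthesis genes Mvd (-0.65 ± 0.11) and Fdps (-0.60 ± 0.09) and the sterol exporter Abcg1 (-0.58 ± 0.07) fell. In all 157 genes were higher and 93 lower, and the total of 250 fell to 142 without oleic well 3 and to 164 and 151 without runs 1 and 3. Cholesterol synthesis genes fell (6 of 18 over all genes tested and 8 adjusted over the list alone; 1.22e-11, 0.00225 with an estimated correlation). For ATF4 targets 0 of 17 passed over all genes tested and 0 adjusted over the list alone, with a camera adjusted p of 0.809.

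The mixture wells were compared with wells that held palmitic acid alone. PAOA_M and PA_M wells carry the same labelled dose. Whether that dose is the total or that of each acid is not stated. If it is the total, the mixture held less palmitic acid. The differences below therefore cannot separate an effect of oleic acid from that of a lower palmitic acid dose. With both acids (PAOA_M against PA_M, 4 wells each), Atf3 differed by -1.35 ± 0.33 (adjusted p 0.0274) and Eif4ebp1 by -1.19 ± 0.25 (adjusted p 0.00644), both lower in the mixture. Cpt1a did not pass, at 0.08 ± 0.16 with a 95% interval from -0.25 to 0.40. In all 11 genes were higher and 25 lower, and the total of 36 fell to 21 without PA_M well 1. The Atf3 call was lost without any 1 of 5 wells: PA_M well 2 (0.0694), 3 (0.135) or 4 (0.0564), or PAOA_M well 3 (0.15) or 4 (0.0520). Without runs 1, 2 and 3 the total was 13, 2 and 13; the Atf3 call was lost without run 2 (0.0903), 3 (0.303) or 4 (0.0664), and that of Eif4ebp1 without run 1 (0.0809), 2 (0.0713) or 3 (0.0556). With array weights 0 genes passed (limma), and these 2 genes had adjusted p of 0.196 and 0.176. ATF4 targets were lower as a list (6 of 17 over all genes tested and 11 adjusted over the list alone; 2.75e-18, 2.09e-04 with an estimated correlation), as were cholesterol synthesis genes (5 of 18 over all genes tested and 9 adjusted over the list alone; 6.86e-18 and 1.73e-04).

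In OA_M against PA_M wells, Atf3 differed by -1.51 ± 0.33, Eif4ebp1 by -1.38 ± 0.25, the transaminase gene Gpt2 by -1.22 ± 0.23 and the phosphatase subunit gene Ppp1r15a by -1.12 ± 0.25, while the metallothionein Mt1 was higher (0.87 ± 0.19). Cpt1a did not pass (0.12 ± 0.16, 95% interval from -0.20 to 0.44). Hspa5 was lower by a call that 7 single wells decided: its change of -0.35 had adjusted p of 0.194, 0.0568, 0.0843 and 0.0962 without PA_M wells 1 to 4 and 0.0949, 0.0936 and 0.217 without OA_M wells 1 to 3. In all 19 genes were higher and 73 lower, and the total of 92 fell to 51, 56 and 43 without PA_M wells 1, 2 and 4 and to 39 without OA_M well 3. It was 28, 47 and 57 without runs 1, 3 and 4, where calls were lost for Ppp1r15a without run 1 (0.106), Atf3 without run 3 (0.140) and Hspa5 without run 1 (0.328), 2 (0.109), 3 (0.267) or 4 (0.0517). OA_M differed from library oleic acid wells in 0 genes by limma, with 671 at an unadjusted p under 0.05, and PAOA_M from OA_M wells in 24 genes higher and 13 lower.

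**Figure D3:**
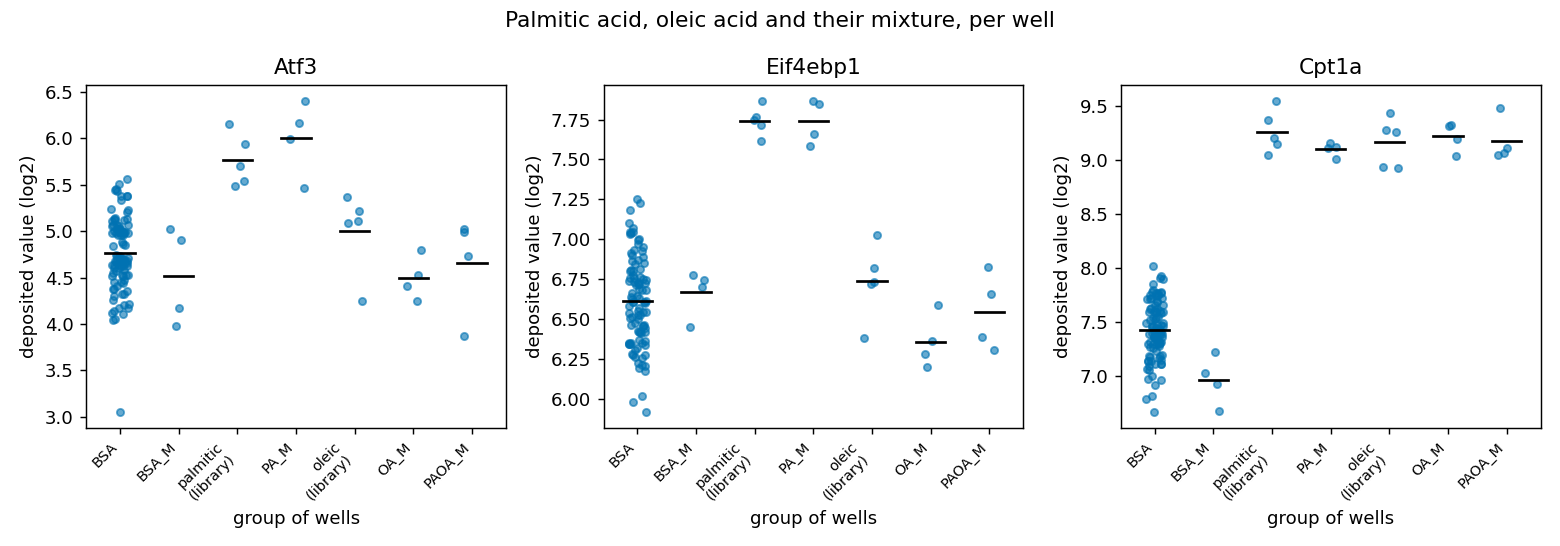
Deposited log2 values of Atf3, Eif4ebp1 and Cpt1a in each well of 7 groups, with black lines at the group means. The mean differences of PAOA_M from PA_M wells were -1.35 for Atf3, -1.19 for Eif4ebp1 and 0.08 for Cpt1a.

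Erucic acid (22 carbons, 1 Z double bond, 6 wells) raised Dusp4 by 2.54 ± 0.15, Cckbr by 2.36 ± 0.16, Egr1 by 2.17 ± 0.19, Cxcl12 by 2.0 ± 0.16, the growth-signalling factor Etv5 by 1.98 ± 0.15 and osteopontin, Spp1, by 1.94 ± 0.19. Gcg (1.41 ± 0.10), Cpt1a (1.12 ± 0.10) and Hspa5 (0.42 ± 0.06) rose less. Aqp4 (-1.39 ± 0.18), the neuronal pentraxin Nptx1 (-1.11 ± 0.09), the sterol exporter Abca1 (-1.07 ± 0.10) and Cmip (-0.27 ± 0.07) fell. In all 1043 genes were higher and 1003 lower. Immediate early genes rose (8 of 10 over all genes tested and 9 adjusted over the list alone; 1.21e-12, 2.75e-07 with an estimated correlation). The ER chaperone list rose as well (12 of 13 over all genes tested and 13 adjusted over the list alone; 7.08e-14 and 1.35e-05). Proliferation genes fell by camera (0.0240) but not with an estimated correlation (0.420). Of 6 markers of unrelated cell types only Vim, a mesenchymal filament gene, passed (0.95 ± 0.15).

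Arachidonic acid (20 carbons, 4 double bonds, 6 wells) raised Gstp1 by 1.74 ± 0.10, the haem oxygenase Hmox1 by 1.33 ± 0.08, the NRF2 target Pir by 1.26 ± 0.11 and Cpt1a by 0.83 ± 0.10. Fdps fell (-0.81 ± 0.08). In all 150 genes were higher and 154 lower, and the total of 304 fell to 192 without arachidonic well 2. NRF2 targets rose (7 of 10 over all genes tested and 9 adjusted over the list alone; 4.20e-31, 2.14e-21 with an estimated correlation) and cholesterol synthesis genes fell (13 of 18 over all genes tested and 15 adjusted over the list alone; 6.31e-39 and 1.03e-09).

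Docosahexaenoic acid (22 carbons, 6 double bonds, 5 wells) raised Gstp1 by 1.91 ± 0.11, Hmox1 by 1.55 ± 0.08, Pir by 1.21 ± 0.12, the redox-related gene Htatip2 by 1.04 ± 0.09 and Cpt1a by 0.59 ± 0.11. The transcriptional inhibitor Id3 (-1.02 ± 0.09) and the replication helicase subunit gene Mcm7 (-0.50 ± 0.06) fell. In all 169 genes were higher and 265 lower, and the total of 434 fell to 278 without well 2 and to 289 without run 1. NRF2 targets rose (5 of 10 over all genes tested and 8 adjusted over the list alone; 2.66e-25 and, with an estimated correlation, 1.04e-17). ER chaperones fell by camera (0.00287), a call lost with an estimated correlation (0.121).

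Isomer pairs asked what the geometry of a double bond changes. Over 12 pairs, E isomers had higher Fdps (0.51 ± 0.03), Abca1 (0.47 ± 0.04) and Mvd (0.44 ± 0.04) than their Z isomers, and lower Fcer1g, an immune receptor subunit gene (-0.30 ± 0.06). The mean Cpt1a difference did not pass (0.05 ± 0.04, 95% interval from -0.03 to 0.13), and single pairs passed as higher in 1 and lower in 1. Cholesterol synthesis genes were higher (18 of 18 over all genes tested and 18 adjusted over the list alone; 1.10e-143, 3.37e-31 with an estimated correlation), whereas the rise of ATF4 targets by camera (3.44e-06) was lost with it (0.0913). In all 98 genes were higher and 28 lower. The total of 126 fell to 63 without the 6-octadecenoic pair and rose to 208, 212 and 245 without the 10-pentadecenoic, 11-eicosenoic and 9,12-octadecadienoic pairs. Single pairs had from 1 to 953 changed genes (median 58), and Fdps passed as higher in 4 of the 12. With the pair as the unit, the mean of the cholesterol list was higher in 11 of 12 pairs (exact two-sided sign-flip p 0.00146), but the number of changed genes did not stand out, since 54 of 100 draws with the signs of whole pairs reassigned gave as many.

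**Figure D4:**
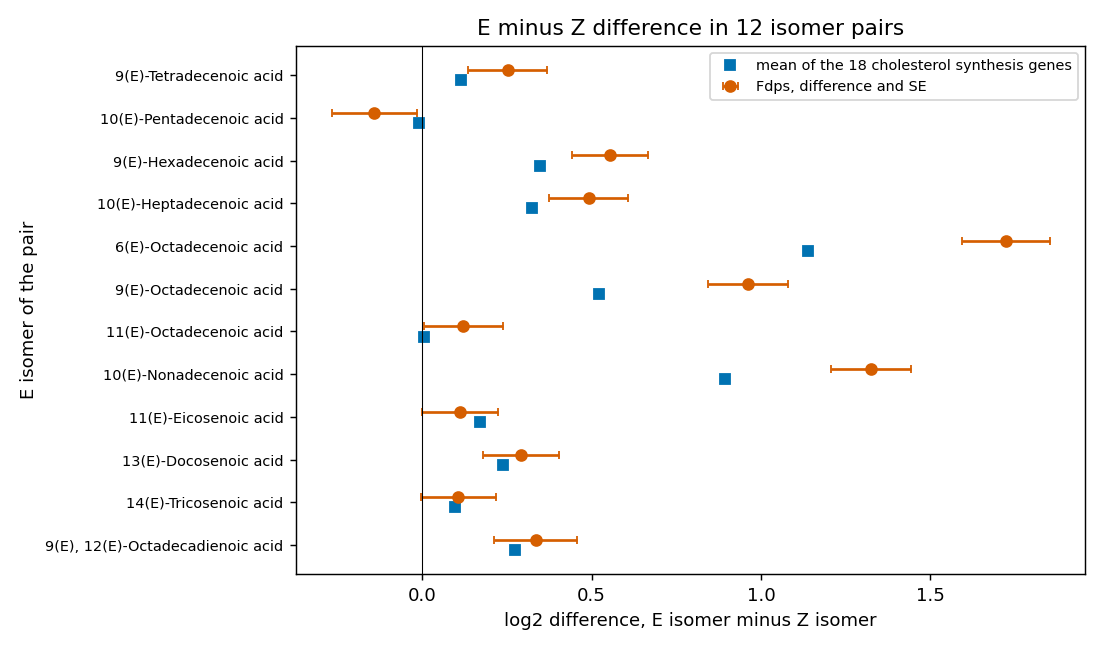
Difference between the E and the Z isomer in 12 pairs on the log2 scale, for Fdps (circles with standard errors) and for the mean of 18 cholesterol synthesis genes (squares). The list mean was higher in the E isomer in 11 of 12 pairs.

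Elaidic against oleic acid had higher Abca1 (1.11 ± 0.14) and Fdps (0.96 ± 0.12) and lower Cox6a2 (-1.06 ± 0.22), with 33 genes higher and 39 lower (40 and 43 in all without runs 1 and 3). Cholesterol synthesis genes were higher (9 of 18 over all genes tested and 14 adjusted over the list alone; 8.00e-36 and, estimated, 5.42e-09). Brassidic against erucic acid had lower Cox6a2 (-2.09 ± 0.21), Dusp4 (-1.95 ± 0.21), Cckbr (-1.94 ± 0.23), Cxcl12 (-1.88 ± 0.21), Egr1 (-1.43 ± 0.26) and Gcg (-1.33 ± 0.14), and higher Aqp4 (1.24 ± 0.24) and Abca1 (1.09 ± 0.13), with 322 genes higher and 389 lower. Here the cholesterol synthesis call (3.38e-05) was lost with an estimated correlation (0.109), while immediate early genes were lower under both (1.16e-12 and 1.80e-07). Vim was lower as well (-0.69 ± 0.21), a call lost without erucic well 3 (adjusted p 0.125), brassidic well 6 (0.0855), or run 3 (0.175) or 6 (0.127).

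Saturated acids were compared with Z monoenes of equal length in 8 pairs. Atf3 (1.31 ± 0.10), Egr1 (1.18 ± 0.10), the cationic amino acid transporter Slc7a3 (1.17 ± 0.11), Ppp1r15a (1.04 ± 0.07), Eif4ebp1 (1.02 ± 0.08), Herpud1 (0.57 ± 0.04) and Hspa5 (0.30 ± 0.03) were higher in the saturated acids. The ubiquitin ligase gene Rnf145 (-0.58 ± 0.05) and Aqp4 (-0.53 ± 0.09) were lower. In all 726 genes were higher and 662 lower, a total of 1388 that fell to 811 without the 19-carbon pair. Single pairs had 82 to 1529 changed genes (median 880.5), Atf3 passed as higher in 5 of 8, and Slc7a3 as higher in 6 and lower in 1. The Cpt1a mean difference was 0.01 ± 0.05 and took either sign when pairs were left out, from -0.13 to 0.18, and passed without the 20-carbon pair (adjusted p 0.00788). ATF4 targets were higher (15 of 17 over all genes tested and 15 adjusted over the list alone; 2.23e-60 and, estimated, 1.51e-12). With the pair as the unit, the mean of that list was higher in 6 of 8 pairs and the exact two-sided sign-flip p was 0.0781, and 19 of 100 sign draws gave as many changed genes.

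Along the 12 saturated acids from 10 to 21 carbons, the change per carbon was 0.17 ± 0.02 for Egr1, 0.13 ± 0.02 for Atf3, 0.12 ± 0.01 for Cckbr, 0.10 ± 0.01 for Sdf2l1 and 0.08 ± 0.00 for Hspa5. The slopes of Egr1 and Atf3 do not mean a steady rise. Against BSA, dodecanoic acid (12 carbons) had Atf3 at 2.50 ± 0.20 and Egr1 at 1.88 ± 0.19. Stearic acid (18 carbons) had them at 1.27 ± 0.20 and 1.62 ± 0.19. Sdf2l1 (-0.70 ± 0.11 and 0.72 ± 0.11) and Hspa5 (-0.18 ± 0.06 and 0.55 ± 0.06) were higher in stearic than in dodecanoic acid. In all 488 genes had a positive and 223 a negative slope, and the total of 711 rose to 1078 without heneicosanoic acid and fell to 463 without run 4. When lengths were reassigned among the 12 acids, 35 of 100 draws gave as many. ER chaperones rose with length (13 of 13 over all genes tested and 13 adjusted over the list alone; 1.29e-66, 1.43e-22 with an estimated correlation), whereas the ATF4 call (7.07e-06) was lost with it (0.114). These list p-values, and those for double bonds below, take wells as replicates and leave out the variation between acids. No list was tested along either slope with the acid as the unit. Along the number of double bonds at 20 carbons, the slope was 0.44 ± 0.02 for Gstp1, 0.33 ± 0.02 for the related Gstm1, 0.22 ± 0.02 for Hmox1, -0.63 ± 0.05 for Slc7a3, -0.58 ± 0.05 for Atf3, -0.14 ± 0.03 for Vim and 0.07 ± 0.02 for Cmip. Here 1027 genes rose and 1056 fell, with all 18 cholesterol synthesis genes falling (1.26e-54 and, estimated, 5.62e-13), and 21 of 100 draws with the numbers of double bonds reassigned among the acids gave as many. The 18-carbon series (8 acids, 41 wells), named in advance as the repeat, had 635 genes rising and 746 falling, and of 951 genes that passed in both series 945 had one direction in both and 6 did not. Gstp1 (0.46 ± 0.03), Gstm1 (0.42 ± 0.02), Hmox1 (0.32 ± 0.02), Slc7a3 (-0.32 ± 0.06) and Atf3 (-0.33 ± 0.06) passed at 18 carbons too, while Cmip (0.04 ± 0.02, adjusted p 0.358) and Vim (-0.08 ± 0.05, 0.294) did not. A shared negative slope does not mean a steady fall of ATF4 targets in both series. Their mean differed by -0.60 for eicosanoic minus 11(Z)-eicosenoic acid, but by 0.58 for stearic minus oleic acid.

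Of 14 other structural pairs, 3 had 0 changed genes by limma: tridecanoic against 12-tridecenoic acid (553 at an unadjusted p under 0.05), 11(Z)- against 9(Z)-octadecenoic acid (587) and gamma- against alpha-linolenic acid (706). Summed over the 14 pairs there were 10448 calls, in which a gene is counted in each pair where it changed. The largest part, 3704, came from 12-methoxydodecanoic against dodecanoic acid. Pairs differing in a terminal alkene otherwise had 1062 and 1975, the 9 pairs differing in bond position had a median of 7 and a highest of 2359 (8(Z)- against 11(Z)-eicosenoic acid), and an added dimethyl group gave 183.

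The 3 acids described next were picked after their counts were seen. All were high, but 11(Z)-eicosenoic (3784) and 14(E)-tricosenoic acid (3627), which lie above dodecanoic acid (3449), are not described further. Dodecanoic acid (6 wells) raised Slc7a3 by 4.46 ± 0.21, Eif4ebp1 by 3.17 ± 0.15 and Cxcl12 by 2.99 ± 0.16, while the islet peptide gene Ucn3 changed by -1.81 ± 0.10, Sdf2l1 by -0.70 ± 0.11 and Cmip by -0.50 ± 0.07. Of the 6 markers of unrelated cell types Col1a1 passed (0.48 ± 0.15), a call lost without well 5 (adjusted p 0.0625) or run 5 (0.0923). 12-Methoxydodecanoic acid (5 wells) raised Atf3 by 4.42 ± 0.22, Ppp1r15a by 4.27 ± 0.16, Eif4ebp1 by 3.80 ± 0.16 and the lipid droplet gene Plin2 by 2.1 ± 0.13. In it the collagen gene Col6a3 changed by -3.75 ± 0.08, Gcg by -2.99 ± 0.11, the glucose transporter Slc2a2 by -2.43 ± 0.08, Sdf2l1 by -2.03 ± 0.12, the ER-secreted factor Manf by -1.76 ± 0.07, Hspa5 by -0.73 ± 0.06 and Ins2 by -1.76 ± 0.14. Standard deviations over its 5 wells were 0.68, 0.57 and 1.05 for Col6a3, Gcg and Ins2, against 0.16, 0.21 and 0.27 over BSA wells. That of Manf was 0.12 against 0.13. Some genes thus varied more between wells of this acid than the pooled errors show. Its ATF4 targets rose (15 of 17 over all genes tested and 15 adjusted over the list alone; 2.38e-26 and, estimated, 5.95e-06), while its ER chaperones fell with a median of -1.24 (12 of 13 over all genes tested and 12 adjusted over the list alone; 5.14e-14 and 1.79e-05). Among the markers of unrelated cell types Vim (1.21 ± 0.17) and the endothelial gene Pecam1 (0.39 ± 0.15) rose and the collagen genes Col3a1 (-0.48 ± 0.14) and Col1a2 (-0.44 ± 0.16) fell. Of these calls only that on Vim held without each well; Pecam1 lost it without well 1 (0.0953), 3 (0.0739) or 5 (0.147), Col3a1 without well 3 (0.157) and Col1a2 without well 1 (0.114) or 5 (0.127). Against dodecanoic acid, Vim differed by 0.95 ± 0.22, Gcg by -3.61 ± 0.14, Manf by -1.63 ± 0.10, Atf3 by 1.92 ± 0.29 and the clock repressor Bhlhe40 by 2.81 ± 0.20, over 3704 changed genes. 5(Z)-Eicosenoic acid (6 wells) raised Slc7a3 by 5.07 ± 0.21, Atf3 by 3.97 ± 0.20, Eif4ebp1 by 3.92 ± 0.15 and the sterol synthesis gene Sqle by 1.41 ± 0.06, while Ucn3 changed by -2.93 ± 0.10 and Cmip by -0.65 ± 0.07. Of the 6 markers of unrelated cell types only Vim passed in it (1.83 ± 0.15). LXR targets in this acid had a median of 0.01, a mean of -0.44 and a downward camera test (0.0486) that was lost with an estimated correlation (0.131).

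The drug wells served as positive controls for ER stress. In wells labelled tunicamycin 5 ng/ml (4 wells), the prostaglandin synthase gene Ptgs2 rose by 4.60 ± 0.24, Slc7a3 by 4.21 ± 0.26, Sdf2l1 by 3.03 ± 0.13, Herpud1 by 2.78 ± 0.09, the ER calcium-binding gene Calr by 2.04 ± 0.07 and Hspa5 by 1.85 ± 0.07, and Slc2a2 changed by -1.10 ± 0.09. In wells labelled thapsigargin 0.000001 mM (4 wells), Slc7a3 rose by 2.88 ± 0.26, Eif4ebp1 by 1.80 ± 0.18, Sdf2l1 by 1.35 ± 0.13, Herpud1 by 1.15 ± 0.09 and Hspa5 by 0.91 ± 0.07, and the uridine phosphorylase Upp1 changed by -1.16 ± 0.11. The numbers of changed genes ran against the labels: wells labelled tunicamycin 5000, 500, 50 and 5 ng/ml had 5, 9, 1517 and 3070. Those labelled thapsigargin 0.001, 0.0001, 0.00001 and 0.000001 mM had 0 (3 wells, 775 genes at an unadjusted p under 0.05 by limma), 37, 59 and 1299. The 5 genes at 5000 ng/ml became 14, 2, 2 and 11 without wells 1 to 4, and 10, 2, 3, 27, 3 and 3 without runs 1 to 6. The 0 at 0.001 mM became 1 without drug well 1 or 2, without some single BSA wells and with the runs as a block, and 1, 2 and 1 without runs 1, 2 and 4.

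**Figure D5:**
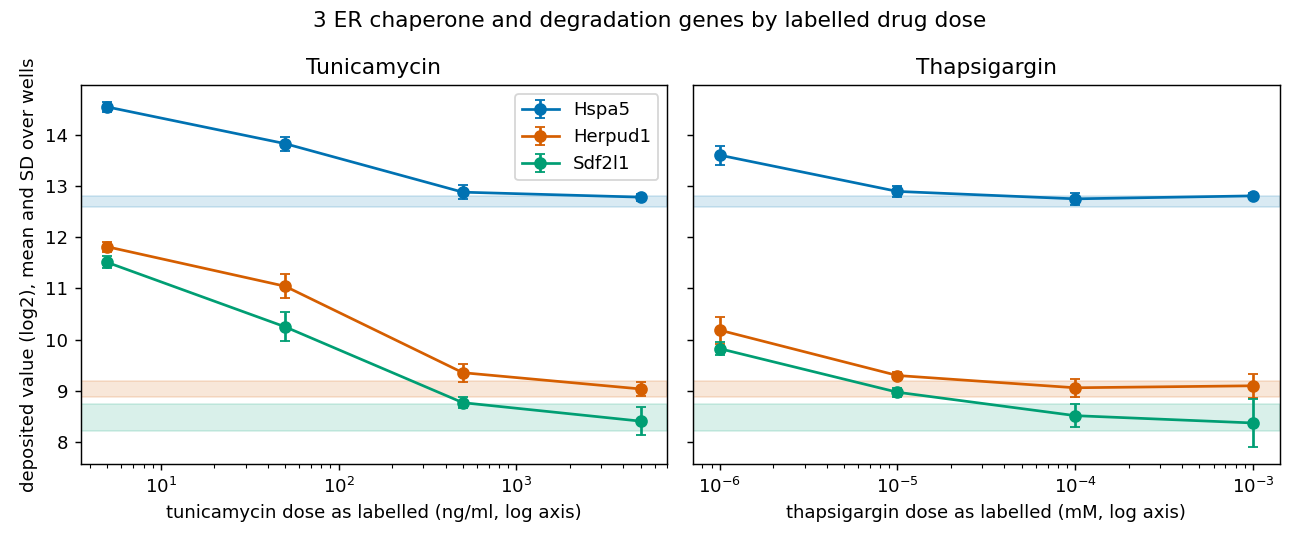
Deposited log2 values (mean and standard deviation over wells) of Hspa5, Herpud1 and Sdf2l1 by labelled dose on a log axis, with bands for the mean and standard deviation of BSA wells. The highest values sit at the lowest labelled doses, 5 ng/ml of tunicamycin and 0.000001 mM of thapsigargin.

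Control comparisons set the background. The columns labelled media differed from BSA wells in 0 genes by limma, with 7 at an unadjusted p under 0.05, which is 0.0620% of the genes tested and far below the share that chance gives. Each of the 6 lay 0.0946 to 0.141 (root mean square, log2) from the BSA mean, whereas the closest BSA well lay at 0.187, and regression on the 98 BSA columns put a weight of 0.984 to 1.05 on those of the media column's own run of table columns. The 0 therefore does not measure the effect of BSA. The BSA_M wells (4 wells, whose treatment label is empty) differed from BSA wells in 1 gene higher and 3 lower, and 7 of 100 splits of the wells gave as many. That count of 4 became 2, 9, 2 and 12 without BSA_M wells 1 to 4, and 7 or 8 without some single BSA wells, and 2, 28, 2, 13 and 2 without runs 1 to 5. PA_M against BSA_M wells gave 215 genes higher and 176 lower. The wells labelled BSA under the library code K00392230 (5 wells) did differ: Cpt1a was 1.94 ± 0.11 higher, Dusp4 1.37 ± 0.17, Gcg 0.92 ± 0.11 and Slc25a20 0.88 ± 0.10, with 191 genes higher and 109 lower. Without K00392230 well 1, 2 or 3 the total of 300 fell to 142, 187 and 160, and without runs 1 and 4 to 130 and 163. Its ER chaperones were higher (6 of 13 over all genes tested and 9 adjusted over the list alone; 7.35e-10 and, estimated, 5.29e-04), while its cholesterol synthesis call (4.43e-05) was lost with an estimated correlation (0.0788).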

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

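The tests of the dose labels, of cell loss, of plate position, of a general shift and the splits within runs were chosen after the results were seen; the other tests of explanations in this part were set before the values they measure were seen. In 15 of 256 groups of 4 to 10 wells, the highest or lowest well stood apart from the rest by Dixon's criterion, which chance alone meets in about 1 in 20 groups. In palmitic acid 1 well stood high for Hyou1 (11.7) and 1 low for Gstm1 (7.87) and Ffar1 (8.94), and in PA_M wells 1 stood high for Egr1 (6.65). Stearic acid had low wells for Acvr1c (10.3) and Slc40a1 (8.5), oleic acid for Cox6a2 (5.32), and docosahexaenoic acid a high one for Gstp1 (12.1) and a low one for Acsl4 (7.30). PAOA_M had a high well for Cpt1a (9.49), brassidic acid for Egr1 (6.90) and K00392230 for Acadl (9.18). Tunicamycin 5 ng/ml had high wells for Hspa5 (14.7) and Slc7a3 (9.08), and thapsigargin 0.000001 mM for Sdf2l1 (10.0).

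The difference between E and Z isomer was itself tested between the 22-carbon and the 18-carbon pair. It differed for 77 genes (limma), 25 higher and 52 lower, among them Sphkap (-1.07 ± 0.15), Cckbr (-1.90 ± 0.33), Cxcl12 (-1.73 ± 0.31) and Dusp4 (-1.68 ± 0.30). These genes were chosen after their values were seen.

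The wells with the lowest labelled doses of tunicamycin and thapsigargin changed most. Library scaling is argued against by a difference of 1.39 between 5 and 5000 ng/ml wells in the mean of the ER chaperones after quantile normalization. Dose labels in reversed order may be the cause: the chaperone mean fell with the labelled dose over tunicamycin wells (Spearman's rho -0.946) and thapsigargin wells (-0.877). That relation was seen before it was tested. Cell loss alone is argued against for tunicamycin, since cells that remain at a higher dose would keep the rise: the chaperone mean at 5000 ng/ml was 0.0327 above BSA (95% interval from -0.156 to 0.222), against 1.45 at 5 ng/ml. For thapsigargin it stays open, with 0.0109 at 0.001 mM (3 wells, -0.421 to 0.443) against 0.680 at 0.000001 mM, an interval that reaches over 50% of that rise. No value measures the number of cells, so remaining cells that do not respond are not excluded, and no biological explanation was tested.

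The wells labelled BSA under K00392230 differed from other BSA wells. Plate position stays open for the number of changed genes, since the BSA position H1 gave 291 against their 300. The largest change of any gene at a BSA position was 0.905 (H1), and that of Cpt1a was 0.364 (H12). Both lie below the Cpt1a rise of these wells. Whether some wells held a fatty acid stays open too, with 2 of 5 wells closest to an acid group (stearic and dimethyleicosadienoic acid). That comparison leans towards BSA, whose mean rests on 98 wells, against 4 to 6 for each acid. The codes of the other BSA wells begin with CNT, whereas these wells carry a code of the form used for the library acids. Carry-over stays open as well, since the best of the 5 surrounding acids (erucic, r 0.530) ranked 2 of 62 after stearic acid (0.555). No biological explanation was tested.

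In 12-methoxydodecanoic acid ATF4 targets rose while ER chaperones fell. Scaling is argued against by a chaperone change of -1.0 after quantile normalization, and single deviating wells by 0 wells within the range of BSA wells. A shift common to all genes would leave the gap between the mean changes of the lists at 0. The gap was 3.12 (standard deviation over wells 0.264). It follows from the opposite directions that define the pattern, so it is no separate test of such a shift. A response of the cells to this acid may remain as a hypothesis, found and tested on the same data.

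For single groups, splits of the same wells tested whether chance could give as many changed genes, and counts include the real split. Few or no other splits gave as many for palmitic (1 of 100 splits as large, real 735, highest other 662), stearic (1 of 100, 1465 and 182), oleic (1 of 100, 250 and 213), erucic (1 of 100, 2046 and 54), arachidonic (2 of 100, 304 and 309), docosahexaenoic acid (1 of 100, 434 and 48) and PA_M (1 of 100, 785 and 334). The same was found for PAOA_M (1 of 35, 36 and 26), OA_M (1 of 35, 92 and 2), elaidic (1 of 100, 72 and 27), brassidic acid (1 of 100, 711 and 259), K00392230 (1 of 100, 300 and 235) and the number of acids above the background (1 of 50, 32 and 13). The number of splits limits how small these shares can be, and they were not adjusted over the comparisons. In the other splits treated wells fall among the control wells. The shares therefore make chance unlikely but do not exclude it. Other groups were picked because their counts were high, so their shares do not allow for that choice and leave chance open to that extent: dodecanoic (1 of 100, 3449 and 807), 12-methoxydodecanoic (1 of 100, 5332 and 1738), its difference from dodecanoic (1 of 100, 3704 and 3117), 5(Z)-eicosenoic acid (1 of 100, 4614 and 3108), tunicamycin 5 ng/ml (1 of 100, 3070 and 262) and thapsigargin 0.000001 mM (1 of 100, 1299 and 722). With wells swapped only within runs, the real count was again the highest for elaidic (1 of 32, highest other 31) and brassidic acid (1 of 32, 239), while 8 splits were too few to decide for PAOA_M (highest other 11) and OA_M (1). Each treated group sat at 1 plate position, which no split holds fixed. The BSA position H1 alone gave 291 changed genes, so position is not excluded for the counts of oleic acid, PAOA_M, OA_M and elaidic acid, which lie below it, nor for those of arachidonic acid (304), K00392230 (300) and docosahexaenoic acid (434), which fell to 192, 142 and 278 without 1 well.

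Chance could not be excluded for tunicamycin 5000 ng/ml (11 of 100, real 5, highest other 438) and BSA_M (7 of 100, 4 and 788). For thapsigargin 0.001 mM (highest other 478) and media (101) the real count was 0, which any split reaches (100 of 100), so the splits decide nothing there. Splits that give several times the real count point to a structure among the wells, such as BSA wells that stand apart. With whole pairs or acids as the unit, chance could not be excluded either for the counts of E minus Z (54 of 100, 126 and 931), saturation (19 of 100, 1388 and 3211), chain length (35 of 100, 711 and 2036) and double bonds at 20 carbons (21 of 100, 2083 and 4218), where the highest other assignment gave more than the real one. For E minus Z it gave several times as many, which points to a structure among the acids.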

How the results depend on the processing

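The residual components, the runs as a block, each run left out, the fit without 3 far BSA wells (at F8, H1 and H11) and the leaving out of wells, pairs or acids were chosen after seeing the data; the other alternatives were planned. Of 289 gene results, all 289 had the same direction and call under upper-quartile scaling and robust moderation, 288 with the runs as a replicate block and without the far BSA wells, 286 with residual components, 285 with only the groups compared, 284 under quantile normalization and 276 with array weights. A mean of at least 20 (4.32 on the log2 scale) left out the results on Vim, Col1a1, Col1a2, Col3a1 and Pecam1, with means of 3.76 to 4.08. Of the 279 results still tested 278 did. Of 192 against BSA, 189 did with BSA wells of columns 5 and 8 only and 175 with media columns as control. Of 1990 recorded leave-one-out results 1906 did, 69 lost and 5 gained a call. Of 1734 results without 1 run 1655 did, 71 lost and 1 gained a call. The residual components could not change any direction, since they were taken after the group means and leave every difference as it was. Counts not given below were within 1.5 times the reported value. The median of all genes moved by at most 0.0287 under either scaling. Where no reason is given, the cause was not tested.

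Thapsigargin 0.001 mM had 0 changed genes, and 1 with a mean of at least 20, upper-quartile scaling, the runs as a block or without the far wells, and 2 under quantile normalization or with components. Tunicamycin 5000 ng/ml had 5 (3 lower with a mean of at least 20, 1 with array weights, 48 with components, 16 with columns 5 and 8, 0 by limma with media). BSA_M had 4 (8 with a mean of at least 20, 10 under quantile normalization with 1 higher and 9 lower, 9 under upper-quartile scaling, 27 with array weights with 10 and 17, 93 with components with 49 and 44, 0 with media). Media against BSA had 0, with 1 under quantile normalization and 4 with array weights, which ran from 0.177 to 7.07 and gave the media columns 2.86 to 7.07 and no other column over 2.08. Array weights gave palmitic acid 488, docosahexaenoic acid 726, PAOA_M against PA_M 0 and OA_M against PA_M 58. They put 54 acids above the background, and the median BSA position as threshold put all 62 there.

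Residual components (2.89, 2.69 and 1.87% of the variance within groups) gave arachidonic acid 512, docosahexaenoic acid 687, PAOA_M 106 (60 higher and 46 lower, against 11 and 25), OA_M 230 (98 and 132, against 19 and 73), K00392230 554, E minus Z 287, elaidic 138 and a median per acid of 594.5. These components come from the residuals of the same fit, so they lower the residual spread by construction. The higher counts are therefore no independent check. With only the groups compared PAOA_M had 16 (1 and 15) and OA_M 77 (32 and 45). PAOA_M had 8 higher and 33 lower under quantile normalization and 6 and 40 under upper-quartile scaling. Media columns as control gave palmitic acid 217, stearic 587, oleic 54 (41 and 13), erucic 991, arachidonic 55, docosahexaenoic 137, PA_M 257 (166 and 91) and K00392230 62 (48 and 14). This control has 6 columns in place of 98, and these do not vary like single wells. If they are averages or pools of BSA wells, gene results that stayed the same under it are no independent check. List calls were 117, 118 with the block, and 80 with an estimated correlation, 131 with fry, 116 under quantile normalization and 113 under upper-quartile scaling.

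Under quantile normalization Ins2 changed by 1.07e-14 in 12-methoxydodecanoic acid and 7.11e-15 in dodecanoic and 5(Z)-eicosenoic acid, which holds by construction, since it is the highest gene of all 500 wells. The Cpt1a saturation difference was -0.026 with array weights and -0.13 to 0.18 without single pairs (negative without pairs 1 to 5). Cpt1a was -0.018 to 0.11 for E minus Z (negative without pair 2) and -0.026 to 0.12 for PAOA_M (negative without its well 2). Acsl1 in palmitic acid was 0.030 with columns 5 and 8, 0.00261 with media, and -0.15 to 0.086 without single wells (positive without 1, 3 or 4). Of these only the Cpt1a saturation difference of 0.18, without pair 7, passed.

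Leaving out 1 well, pair or acid gave palmitic acid 546 to 769 changed genes, stearic 1109 to 1493, oleic 142 to 264, erucic 1732 to 2088, arachidonic 192 to 323, docosahexaenoic 278 to 444, PA_M 492 to 797, PAOA_M 21 to 52, OA_M 39 to 90, thapsigargin 0 to 1, tunicamycin 2 to 14, media 0 to 0, K00392230 142 to 318, BSA_M 2 to 12, elaidic 50 to 77, brassidic 581 to 717, E minus Z 63 to 245, saturation 811 to 1973, chain length 479 to 1078 and double bonds 1718 to 2600.

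Leaving out 1 run moved counts by over 1.5 times as follows. Without run 1 oleic acid had 164, docosahexaenoic acid 289, PA_M 473, PAOA_M 13, OA_M 28, thapsigargin 1, tunicamycin 10, K00392230 130, BSA_M 2, elaidic 40 and the median acid 218. Without run 2 PAOA_M had 2, thapsigargin 2, tunicamycin 2 and BSA_M 28. Without run 3 oleic acid had 151, PAOA_M 13, OA_M 47, tunicamycin 3, BSA_M 2 and elaidic 43. Without run 4 OA_M had 57, thapsigargin 1, tunicamycin 27, K00392230 163, BSA_M 13 and chain length 463. Without run 5 tunicamycin had 3 and BSA_M 2, and without run 6 tunicamycin 3 and the median acid 203.5. Directions turned for Acsl1 in palmitic acid (0.045, 0.084 and 0.00397 without runs 1, 3 and 4), the Cpt1a saturation difference (-0.023, -0.010 and -0.00612 without runs 1, 3 and 4) and Cpt1a in PAOA_M (-0.018 without run 2), none of which passed.

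Pseudocounts of 0.5 and 5 (the values are already logarithms), no filter (no gene lay below the minimum), a plate term by name, leaving out named plates, and edgeR or DESeq2 (no whole reads) were not run. The runs as a replicate block gave 44 genes for PAOA_M (16 and 28), 106 for OA_M (26 and 80), 789 for palmitic acid and 140 for E minus Z. The block changed 1 gene call, that on Cmip in palmitic acid (-0.22, adjusted p 0.0327), and 1 list call at the preset correlation, with lysosomal genes passing in docosahexaenoic acid (0.0483 for 0.0802); with an estimated correlation glycolysis genes passed there (0.0311 for 0.0534). It changed no other call. Depth is unknown, so what it limits was not assessed.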

Other observations

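The tests of the media columns and of Cmip were chosen after the results were seen; the others in this part were set before the values they measure were seen. The 6 columns labelled media differed less from the BSA mean than any of the 98 BSA wells did. Their distance was 0.0946 to 0.141 (root mean square, log2), against 0.187 for the closest BSA well and 0.251 for the median one, and the median standard deviation per gene was 0.0961 among them and 0.257 among BSA wells. Regressed on all BSA columns, each media column put a summed weight of 0.984 to 1.05 on the 14 to 17 BSA columns of its own run of table columns and left a residual of 0.0713 to 0.114. As a comparison, the mean deviation of the treated wells of each run from their group means was added to the mean of all BSA wells. This sum put at most 0.317 on the BSA columns of its own run. The BSA mean in it spreads weight evenly over all BSA columns by construction. A single BSA well put a median of 0.245 and at most 0.577 on the others of its run, and its residual was at least 0.185.

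A candidate explanation is that the media columns hold averages or pools of the BSA wells of their run and not single media wells. The lowest weight of 0.984 and the highest comparison weight of 0.317 are what this needs. Less noisy single wells, taken as the BSA mean plus a shared run effect, are argued against by that comparison. The treated wells of a run share its effect. Whether the averaging took place in the tube or in the table cannot be read from the values, and with such columns the data hold no test of media against BSA.

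Further hypotheses concerned the acids as units. The higher cholesterol synthesis genes of E isomers held over pairs (mean of the list 0.34 with a standard deviation of 0.35, higher in 11 of 12 pairs, exact two-sided sign-flip p 0.00146). Higher ATF4 targets in saturated acids were not shown over pairs (mean 0.53, standard deviation 0.63, 6 of 8 pairs, exact p 0.0781). Gstp1 may follow the number of double bonds over the 18 acids with 2 or more of them (Pearson's r 0.567, permutation p 0.0143; Spearman's rho 0.595, p 0.0104; r 0.566 without the 2 acids farthest from the median). Cmip may fall as ATF4 targets rise over the 62 acids (r -0.908, rho -0.846, permutation p 1e-05 for both, the smallest these permutations can give; r -0.871 without the 2 farthest acids). These were the 2 relations computed, with adjusted p of 0.0143 and 2e-05, and the changes of all acids share the BSA wells they are measured against. No biological mechanism was tested.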
